A study of Mus musculus with 12 samples.

How the data were processed

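Whole testes of wild-type (WT) and Topaz1-/- (KO) C57Bl/6N mice were sampled at 15 and 20 days after birth (P15 and P20). Each of the 4 groups held 3 samples that the labels call biological repeats. Per the labels' protocols, total RNA was extracted on columns with DNase I treatment, labelled with biotin and hybridised to 1 Illumina mouse bead array per sample. Per the submitters' processing notes the arrays were read with BeadStudio, whose version is not given in the sources used here. The deposited non-normalized table holds linear intensity values of the 12 arrays as exported, and 0 of its columns belonged to other samples. The authors' processed values are linear intensities after quantile normalization. This was tested by quantile-normalizing the non-normalized intensities, which differed from the authors' values by a median of 6.59e-05 and at most 0.0124 on the log2 scale. Detection p-values, control probes and slide positions are not given in the sources used here. The planned background correction from negative controls (neqc), filters on detection p-values and a slide term could therefore not be run, and the fallback fixed in the design was used.

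The intensities were quantile-normalized over all 12 arrays, an offset of 50 was added and log2 was taken. The values were not background-subtracted, which compresses fold changes. Over the 472 probes that passed at P20, normexp background correction with an offset of 50 or 16 gave log2 changes 1.28 or 1.42 times as large in the median. Background was estimated per array as the mode of the log2 intensities plus 1.645 standard deviations of the values below the mode. Where none of the 3 arrays of the lower group was above background, the fold is given as a lower bound against that threshold ("at least"). Before normalization the median intensity of an array was 128.2 to 143.4. With 3 arrays per group small changes can be missed.

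Probe names were taken from the annotation of the array. Of the probes 34885 had 1 gene symbol, 18 had several and 10378 were not listed there and are called unnamed, and 19057 genes had a named probe. Chromosomes come from the gene table of assembly GRCm38.p6. The probes' own genome build is not given in the sources used here, so no probe coordinates are printed. A gene is represented by its probe of highest mean intensity. Probes of multicopy genes, such as those of the Y chromosome, cannot be assigned to 1 copy.

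All probes were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 group means, 8 residual and 2.14 prior degrees of freedom). The 5 comparisons were KO against WT at P15 and at P20, the difference between these effects, and P20 against P15 in WT and in KO. P-values were adjusted by the Benjamini-Hochberg method over all probes, with a threshold of 0.05. Errors of log2 changes are standard errors (SE) of the fit, and errors of group means are standard deviations (SD) of 3 arrays. Up to 12 rises and 12 falls were named per genotype comparison, 5 for the difference and 6 per age comparison, by size among genes past the threshold, and for genotype only where all 3 KO arrays lay on the same side of all 3 WT arrays. Up to 4 members of a list past the threshold were named, or else the 2 of highest mean. Members named because they passed adjusted over the list alone were chosen after their values were seen.

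The 20 gene lists comprised 17 fixed by name together with the X chromosome (710 measured genes), the Y chromosome (19) and the genes within 5 Mb of Topaz1 (84). The fixed lists, with measured genes of those written, were spermatogonia (20 of 20), early meiotic prophase (27 of 31), pachytene spermatocyte (24 of 25), meiotic G2/M and division (33 of 34), round spermatid (45 of 48), cilium and flagellum axoneme (72 of 87) and piRNA pathway (20 of 21). The others were DNA damage response (26 of 28), p53 targets and apoptosis (23 of 26), sentinels of sex chromosome silencing (19 of 27), Sertoli (21 of 24), Leydig (13 of 15), peritubular (9 of 9), macrophage and leukocyte (17 of 20), endothelium (11 of 11), erythroid (4 of 9) and epididymis (19 of 22). Of the epididymis genes 7 were above background in a whole group, and Clu, written in both this list and the Sertoli list, was not among the measured genes of either. Lists were tested with camera (preset correlation 0.01), again with the correlation estimated from the data, and with fry, each adjusted over the 20 lists. A list of 26 adipocyte genes, 23 of them measured, was written after the rise of Adipoq was seen and is used in the closing section alone.

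Alternatives were the authors' values, quantile normalization on the log2 scale, cyclic loess, 75th percentile scaling, normexp with either offset, filters on dim probes, an intensity trend, array weights, a fit of only the compared groups, the replicate number as a block, the mean over a gene's probes, a fold of at least 2, and leaving out each array. Scaling to the 75th percentile moved the median of all probes by 0.134 on the log2 scale at P15. The comparisons, the model and the other alternatives were fixed before the data were examined. Normexp, cyclic loess, 75th percentile scaling and the filters on estimated background were added afterwards, in place of planned versions that needed control probes or detection p-values. The fit was tested on simulated data of the same size, where 41% of probes changed by log2 0.5 and 90.7% of those changed by log2 1 were recovered, of 300 each over 3 runs, with 33 false calls. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.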

Results

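Gene expression was measured in whole testes of wild-type (WT) and Topaz1-/- (KO) mice of the C57Bl/6N strain at 15 and 20 days after birth (P15 and P20). Topaz1 is named in the series title as a germ cell factor that male meiosis needs. At P15 the oldest germ cells of the first spermatogenic wave are in meiotic prophase, and around P20 the first round spermatids appear. Each of the 4 groups held 3 biological repeats, each hybridised to 1 Illumina mouse bead array, so that 12 arrays entered the comparisons. No probe carried the name or accession of Topaz1 in the annotation used here (0 by either route), so its transcript was not identified and the genotype labels were not checked against it. The annotation did not list 10378 probes, and a Topaz1 probe among these unnamed ones is not excluded. The median intensity of an array was between 128.2 and 143.4, and 47.5% to 51.9% of its probes lay above the estimated background. The small number of arrays, 3 per group, limits the precision.

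Age separated the arrays. The first principal component carried 82.2% of the variance and divided P15 from P20, and the second carried 6.1%. Within a group, arrays correlated with Spearman coefficients of 0.897 to 0.923 across probes, which are not independent replicates, and 0 pairs of arrays held identical values. KO P15 replicate 1 lay at 7.5 on the second component, beside the WT P15 arrays (5.5 to 11.3) and away from the other KO P15 arrays (-14.8 and -20.1). WT P20 replicate 1 lay at 31.2 on the first component, below the other WT P20 arrays (42.7 and 51.5) and the KO P20 arrays (51.4 to 56.9).

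The comparison of KO with WT testes at P15 asks which transcripts the loss of Topaz1 alters early in the first wave. Trf, which encodes the iron carrier transferrin secreted by Sertoli cells, was lower in KO testes, with a log2 change of -0.65 ± 0.06 (SE, n = 3 per group), or 1.57-fold. All 3 KO arrays (8.76 to 8.85 in log2 units) lay below all 3 WT arrays (9.37 to 9.59), and the adjusted p was 0.0191. The unnamed probe ILMN_1257177 had a log2 change of -1.85 ± 0.11 (SE, adjusted p = 0.000337), from 9.43 ± 0.28 (SD, n = 3) in WT to 7.58 ± 0.04 in KO testes, where 2 of 3 arrays were above background. Its gene is not known here, and whether it measures Topaz1 itself was not tested. The Sertoli cell list otherwise showed no shift: of 21 members, 0 rose, 1 fell (Trf) and 20 did not pass, with 1 fall adjusted over the list alone and a camera adjusted p of 0.597.

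The macrophage and leukocyte list was the called list at P15, and it shifted downward (camera adjusted p = 0.000561, adjusted p = 0.314 with an estimated correlation). Of its 17 members 0 rose, 0 fell and 17 did not pass in limma over all probes. The median log2 change was -0.15 (-0.06 without KO P15 replicate 2), and 3 members had a positive change. A fall was found adjusted over the list alone for 1 member, Cd74, the invariant chain of MHC class II molecules, at -0.60 ± 0.14 (SE). The brightest members, Lyz1 and Laptm5, had log2 changes of 0.01 ± 0.18 and -0.38 ± 0.16. In the early meiotic prophase list of 27 members, 0 passed over all probes (camera adjusted p = 0.502). Its 1 rise adjusted over the list alone was Rec114, a partner of the recombination initiation machinery, at 0.45 ± 0.09. The remaining 17 lists had 0 members past the threshold over all probes and 0 adjusted over the list alone, with camera adjusted p between 0.107 (cilium, peritubular) and 0.970 (sex-linked sentinels). Median, mean and camera direction differed in sign for the G2/M, Sertoli, Leydig and X lists, which were not called.

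In limma, 2 probes passed at P15, 0 higher and 2 lower in KO, while 3436 had an unadjusted p under 0.05. The count moved most without KO P15 replicate 1, to 154 probes (48 higher, 106 lower). It was 4 without WT P15 replicate 1, and 1 without WT P15 replicate 2, KO P15 replicate 3 or KO P20 replicate 2. The Trf call ended without WT P15 replicate 2, KO P15 replicate 2 or 3, or KO P20 replicate 2 (adjusted p up to 0.161), and under cyclic loess, a normexp offset of 16, an intensity trend, or a fit of the 2 groups alone, where 0 probes passed. It also ended with KO P20 replicates 1 and 3 left out.

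At P20 the comparison asks how KO testes differ when the first WT germ cells leave meiosis. C2cd4a, a nuclear protein with a C2 domain, was 12.4-fold lower in KO testes, with a log2 change of -3.63 ± 0.46 (SE, n = 3 per group, adjusted p = 0.00698). Chst1, a carbohydrate sulfotransferase, was 10.1-fold lower (-3.34 ± 0.30, adjusted p = 0.00123), and Elfn2, a leucine-rich repeat membrane protein, 3.70-fold lower (-1.89 ± 0.16, adjusted p = 0.00116). Mean log2 intensity of C2cd4a was 12.06 ± 0.12 (SD) in WT and 8.43 ± 0.07 in KO testes, and that of Chst1 was 11.53 ± 0.15 and 8.19 ± 0.06. At P15 the changes of C2cd4a and Chst1 were -0.51 ± 0.46 and -0.93 ± 0.30 (SE, adjusted p = 0.868 and 0.532), and the difference between the ages did not pass (adjusted p = 0.171 and 0.0944). The 2 other probes of C2cd4a did not pass at P20 (log2 -0.05 for each).

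Other transcripts fell to background. Gm20815, a predicted gene of the Y chromosome, was at least 6.56-fold lower in KO testes at P20 (adjusted p = 0.0162), and Gldnos (at least 1.94-fold, adjusted p = 0.000163) and 4930519G04Rik (at least 2.01-fold, adjusted p = 0.000762) were likewise above background on all 3 WT and on 0 of 3 KO arrays. The fold of Gm20815 depends on the array, with log2 intensities of 8.90, 10.77 and 11.11 on WT P20 replicates 1, 2 and 3. The fit pools the spread of a probe over the 4 groups, and Gm20815 was at background with little spread in all groups but WT P20. Its adjusted p therefore rests on a smaller spread than that of the WT P20 arrays. The Y-linked probe cannot be assigned to 1 copy, because much of the mouse Y chromosome consists of near-identical multicopy genes. Above background in both genotypes, Gstt2, a glutathione transferase, fell 2.50-fold (adjusted p = 0.0157), 1700088E04Rik 2.48-fold (adjusted p = 0.0360), and Ifi213, of the interferon-activated p200 family, 2.33-fold (adjusted p = 0.000284). Tsc22d1, a leucine zipper regulator of transcription, fell 1.82-fold (adjusted p = 0.0461), Cdk2ap2, a CDK2-associated protein, 1.69-fold (adjusted p = 0.0309), and Rxylt1, a xylosyltransferase, 1.62-fold (adjusted p = 0.0309). For Ifi213 and Rxylt1 each, 1 of 2 probes had the opposite sign. The unnamed probe ILMN_2707818 had a mean log2 intensity of 11.51 in WT and was above background on 0 of 3 KO P20 arrays (adjusted p = 0.00117). The unnamed probe ILMN_1257177 had a log2 change of -2.68 ± 0.11 (SE, adjusted p = 4.39e-06) and was above background on 2 of the 3 KO P20 arrays.

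The largest rise was that of Ptchd3, a patched-domain protein found in sperm, 3.17-fold higher in KO testes at P20 (log2 1.66 ± 0.23, SE, n = 3 per group, adjusted p = 0.0114). Among the other large rises were Mgll, the monoacylglycerol lipase (2.32-fold, log2 1.22 ± 0.12, adjusted p = 0.00202), Lpl, lipoprotein lipase (2.32-fold, 1.22 ± 0.22, adjusted p = 0.0323), and Gldc, the glycine decarboxylase of mitochondria (2.25-fold, 1.17 ± 0.15, adjusted p = 0.00774). Adipoq, the fat cell hormone adiponectin (2.41-fold, 1.27 ± 0.13, adjusted p = 0.00256), and Cyp2e1, a cytochrome P450 (2.34-fold, 1.23 ± 0.22, adjusted p = 0.0340), were above background on 1 of 3 WT P20 arrays and on all 3 KO P20 arrays. 4931406B18Rik rose 2.41-fold (1.27 ± 0.05, adjusted p = 3.45e-06) and was above background on 2 of 3 WT P20 arrays. Lin7a, a cell polarity scaffold (1.98-fold), Fbxw27 (1.97-fold), D130017N08Rik (1.95-fold), Slc4a8, a bicarbonate transporter (1.95-fold), and Ttll11, a tubulin polyglutamylase (1.93-fold), completed the 12 largest rises, with adjusted p from 0.00123 to 0.0323. Of the probes of Lpl, Lin7a and Fbxw27, 1 of 2, 2 of 4 and 1 of 2 had the opposite sign.

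Defb2 and Adam7, of the epididymis list, were high on 2 of the 3 KO P20 arrays. Defb2 had log2 intensities of 10.83 and 11.14 on KO P20 replicates 1 and 3 and 7.50 on replicate 2, and Adam7 had 8.66, 9.08 and 7.46 in the order 1, 3, 2. The highest WT P20 values, 8.62 and 7.70, were on WT P20 replicate 3. Crisp4, Rnase9, Rnase10, Gpx5, Lcn9 and Pate4 of the same list were above background on 0 of 3 KO P20 arrays. Adipoq was high on all 3 KO P20 arrays (8.78, 9.02 and 8.87) against 7.49, 7.52 and 7.85 in WT, the last on WT P20 replicate 3. Among the P15 arrays Adipoq and Cyp2e1 were highest on WT P15 replicate 2 (8.05 and 8.50). KO P20 replicate 2 had the highest KO P20 values of the erythroid genes Hba-a1 (14.14), Alas2 (9.02) and Slc4a1 (8.45), while Hbb-b2 was at background. Leaving out KO P20 replicates 1 and 3 was chosen after seeing the data, and the 1 remaining KO P20 array, replicate 2, is assumed to vary like the other groups. In that fit 130 probes passed at P20 (113 higher, 17 lower), of which 72 were among the 472. Adipoq, Chst1, Elfn2, Ifi213, Gldnos, 4930519G04Rik, 4931406B18Rik, Lin7a, Slc4a8 and Ttll11 were then still called. The other 14 of the 24 genes of largest change were not, among them C2cd4a (-3.65, adjusted p = 0.130), Gm20815 (adjusted p = 0.238), Ptchd3 (1.59), Mgll (1.18) and Lpl (1.10).

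**Figure D1:**
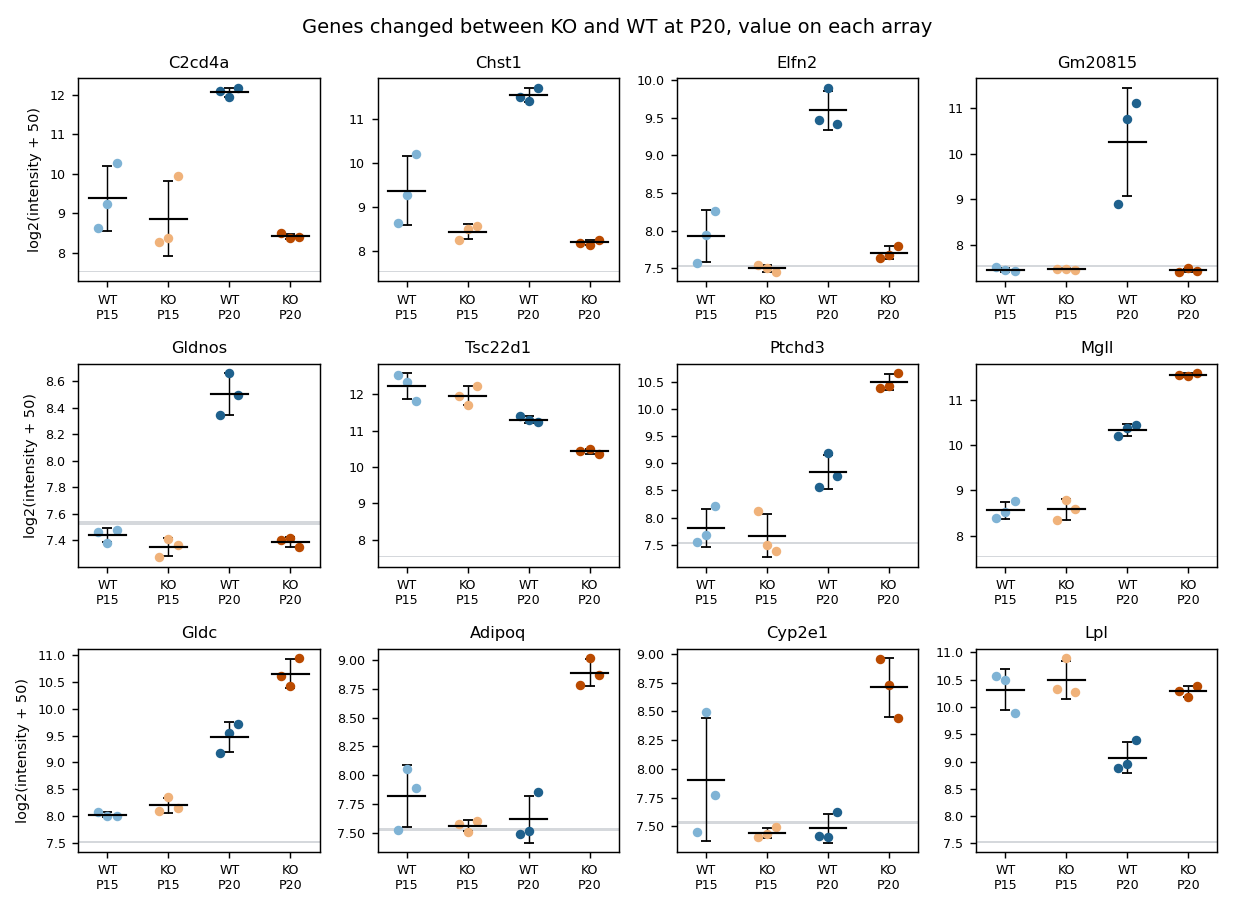
Normalized log2(intensity + 50) of 12 genes on each of the 12 arrays, grouped by genotype and age, with a point per array, a line at the mean and bars of 1 SD (n = 3); the grey band is the range of the background thresholds. C2cd4a and Chst1 lie at 12.06 and 11.53 in WT P20 and at 8.43 and 8.19 in KO P20, and Adipoq rises above the band on all 3 KO P20 arrays.

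The cilium and flagellum list, which also rose with age in WT testes, shifted upward in KO testes at P20. Of 72 measured members of the axoneme list 2 rose, 0 fell and 70 did not pass, with the same counts adjusted over the list alone. The median was 0.16 (0.06 without WT P20 replicate 1, 0.26 without WT P20 replicate 3), and 57 had a positive change. Dnah2, an axonemal dynein heavy chain, rose (log2 0.71 ± 0.09, SE, adjusted p = 0.00806, with 1 of 3 probes opposite), and Cfap43, a flagellum assembly protein, 1.44-fold (0.53 ± 0.10, adjusted p = 0.0336). The list was called up by camera (adjusted p = 1.21e-05, adjusted p = 0.613 with an estimated correlation). In the pachytene spermatocyte list of 24 members, 1 rose, 0 fell and 23 did not pass, with 2 rises adjusted over the list alone. These were Ovol1, a zinc finger factor of pachytene progression (1.33-fold, 0.41 ± 0.08, adjusted p = 0.0397), and Adam3, a sperm surface protein (0.53 ± 0.14). Camera called this list up (adjusted p = 0.0495, adjusted p = 0.626 with an estimated correlation).

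The Sertoli cell list, which also fell with age in WT testes, shifted downward. All 21 members had a negative change at P20, with a median of -0.18 (-0.11 without WT P20 replicate 1). Of these 0 rose, 1 fell and 20 did not pass, and 5 fell adjusted over the list alone. Cst9, a cystatin of Sertoli cells, fell 1.27-fold (log2 -0.34 ± 0.06, SE, adjusted p = 0.0299), and the others were Inha, the inhibin alpha subunit (-0.58 ± 0.17), Rhox5 (-0.58 ± 0.18), Dhh (-0.43 ± 0.13) and Aard (-0.18 ± 0.06). Camera called the list down (adjusted p = 4.1e-06, adjusted p = 0.192 with an estimated correlation), and fry, which tests whether the members move one way, gave an adjusted p of 0.0208. The spermatogonia list (20 members, 0 past the threshold) was also called down (adjusted p = 0.0495, adjusted p = 0.626 with an estimated correlation). Adjusted over the list alone, 3 of its members fell, Kit, the stem cell factor receptor (-0.44 ± 0.09), Uchl1 (-0.73 ± 0.19) and Foxo1 (-0.28 ± 0.08), and 1 rose, Id4, a stem cell marker (0.44 ± 0.13).

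Lists of sex-linked and spermatid transcripts shifted downward at P20. Of 19 Y chromosome genes 0 rose, 1 fell (Gm20815) and 18 did not pass, and 9 fell adjusted over the list alone. These 9 included the multicopy Ssty2, Ssty1 and Sly, above background on 0 of 3 KO P20 arrays, and Gm20867, above it on 2 of 3, whose probes can share copies. Zfy1, a zinc finger gene above background on all P20 arrays, was also among them (-0.23 ± 0.08, SE). Usp9y (0.04 ± 0.16), Kdm5d (0.06 ± 0.05) and Eif2s3y (-0.11 ± 0.18), likewise above background on all P20 arrays, did not pass on either adjustment. The fall was thus not of the Y chromosome as a whole. The Y list was called down (camera adjusted p = 7.62e-06, adjusted p = 0.192 with an estimated correlation; fry adjusted p = 0.0208). Ssty2 had log2 intensities of 8.00, 9.68 and 10.08 on WT P20 replicates 1, 2 and 3 and 7.39 to 7.51 on the KO P20 arrays. As for Gm20815, the pooled spread of the fit was smaller than that of the WT P20 arrays. Of 710 X chromosome genes 0 rose, 5 fell and 705 did not pass, and 2 fell adjusted over the list alone. The 5 were Dmrtc1a (1.35-fold, adjusted p = 0.0464), Gm5072 (1.30-fold, adjusted p = 0.0123), Zfp711 (1.26-fold, adjusted p = 0.0458), AU015836 (1.22-fold, adjusted p = 0.0414) and Gm14594 (log2 -0.27, adjusted p = 0.0255), the last named after its value was seen. The X list was called down (camera adjusted p = 2.26e-05, adjusted p = 0.318 with an estimated correlation) with a median of -0.03.

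The list of sentinels of sex chromosome silencing (19 members, 0 past the threshold) was called down (camera adjusted p = 0.0101, adjusted p = 0.551 with an estimated correlation), with 2 falls adjusted over the list alone, Sly and the X-linked Fmr1nb (-0.89 ± 0.24, SE). In the round spermatid list of 45 members 0 passed over all probes, and camera called it down (adjusted p = 0.00344, adjusted p = 0.626 with an estimated correlation). Its median was -0.06 with 15 positive members, -0.10 without WT P20 replicate 1, -0.04 without WT P20 replicate 3 and 0.00533 under 75th percentile scaling, where camera still called it down. That scaling put the median of all probes at P20 at 0.0626, so the list still lay below it. There were 8 falls adjusted over the list alone, among them Odf1, an outer dense fibre protein (-0.59 ± 0.18), and Spaca1 (-0.45 ± 0.10) and Acrv1, both of the acrosome, with Acrv1 above background on 2 of 3 WT and 0 of 3 KO P20 arrays. The 1 rise was Zpbp2, a zona pellucida binding protein (0.54 ± 0.11). Catsper2, a sperm calcium channel subunit, and Odf2, above background on all 12 arrays, had log2 changes of 0.47 ± 0.24 and 0.33 ± 0.26, which did not pass. Odf1 had log2 intensities of 7.69, 8.33 and 8.63 on WT P20 replicates 1, 2 and 3 and 7.59 to 7.66 in KO, and Acrv1 7.47, 7.99 and 8.19 against 7.41 to 7.47.

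**Figure D2:**
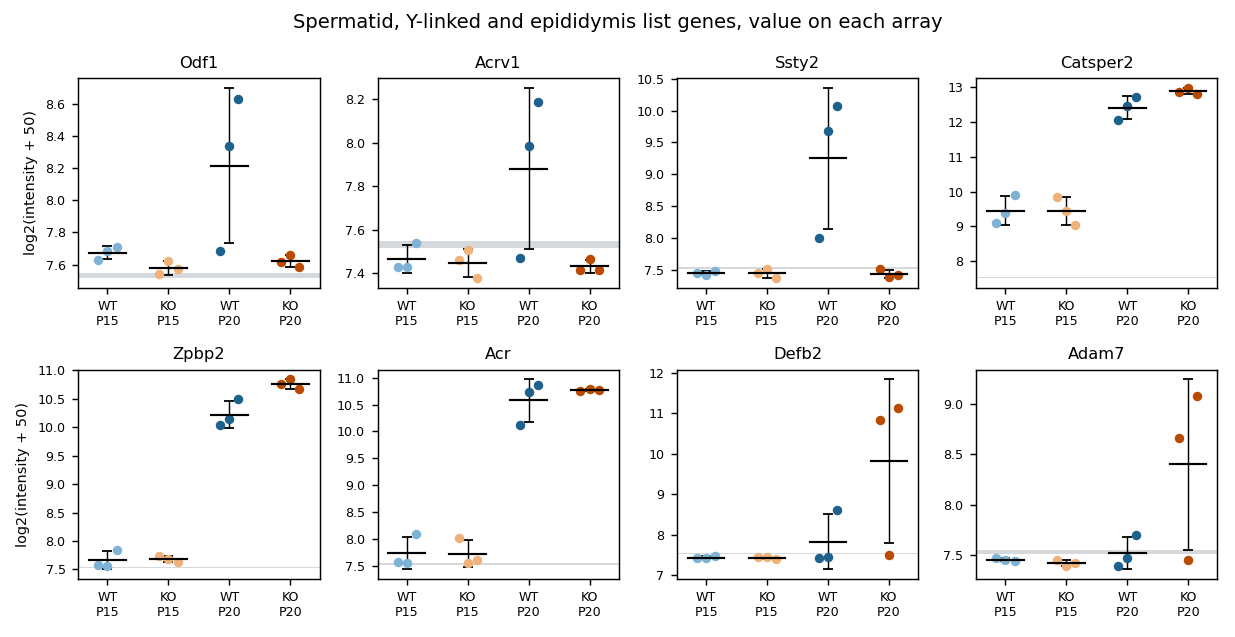
Normalized log2(intensity + 50) of 8 members of the spermatid, Y chromosome and epididymis lists on each of the 12 arrays, grouped by genotype and age, with a point per array, a line at the mean and bars of 1 SD (n = 3); the grey band is the range of the background thresholds. Defb2 and Adam7 are high on KO P20 replicates 1 and 3 and near the band on replicate 2, and Ssty2 lies at 8.00, 9.68 and 10.08 on the WT P20 arrays.

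The G2/M, early meiotic, DNA damage, piRNA and p53 lists were not called by camera at P20. In the G2/M and division list (33 members, 0 past the threshold, camera adjusted p = 0.685), Hspa2 and Cdc20, which drive entry into and exit from division, had log2 changes of 0.23 ± 0.32 and 0.06 ± 0.16 (SE). Adjusted over the list alone, Bub1b (0.29 ± 0.06) rose and Plk1 (-0.85 ± 0.18) and Cdc25a (-0.41 ± 0.09) fell. The early meiotic prophase list (27 members, camera adjusted p = 0.824) and the DNA damage list (26 members, adjusted p = 0.496) had 0 members past the threshold on either adjustment, with Stag3, a cohesin subunit, at 0.47 ± 0.12 and H2ax at -0.10 ± 0.17. The DNA damage list had a median of -0.01, a mean of 0.05 and an upward camera direction. In the piRNA list (20 members, 0 past the threshold, camera adjusted p = 0.548) 1 member rose adjusted over the list alone, Gtsf1 (0.46 ± 0.10), and in the p53 and apoptosis list (23 members, 0 past the threshold, adjusted p = 0.119) 1 fell, Sesn2 (-0.40 ± 0.09), and fry gave an adjusted p of 0.0446.

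The Leydig, peritubular, macrophage, endothelium, erythroid and epididymis lists were not called at P20. Camera adjusted p was 0.742 for Leydig cells (13 members), 0.742 for peritubular and smooth muscle (9), 0.352 for macrophages and leukocytes (17), 0.261 for endothelium (11), 0.442 for erythroid genes (4) and 0.227 for epididymis (19), with 0 members of these lists past the threshold over all probes. Adjusted over the list alone the count was 0 except for Lyz2 of the macrophage list (-0.78 ± 0.16, SE), which shares sequence with Lyz1. Log2 changes were -0.34 ± 0.31 for Insl3 of Leydig cells, 0.18 ± 0.11 for Acta2 of smooth muscle and 0.14 ± 0.61 for Hba-a1, a haemoglobin gene with a near-identical copy, with values from 11.46 to 14.14 on the KO P20 arrays. Of 84 genes within 5 Mb of Topaz1 on chromosome 9, 1 rose, Tmem42 (1.55-fold, 0.64 ± 0.09, adjusted p = 0.0132), 0 fell and 83 did not pass. In this list 3 rose adjusted over the list alone (Tmem42, Exog at 0.44 and Ano10 at 0.35) and 2 fell (Pomgnt2 at -0.39 and Azi2 at -0.31). Camera gave an adjusted p of 0.392 for this neighbourhood.

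**Figure D3:**
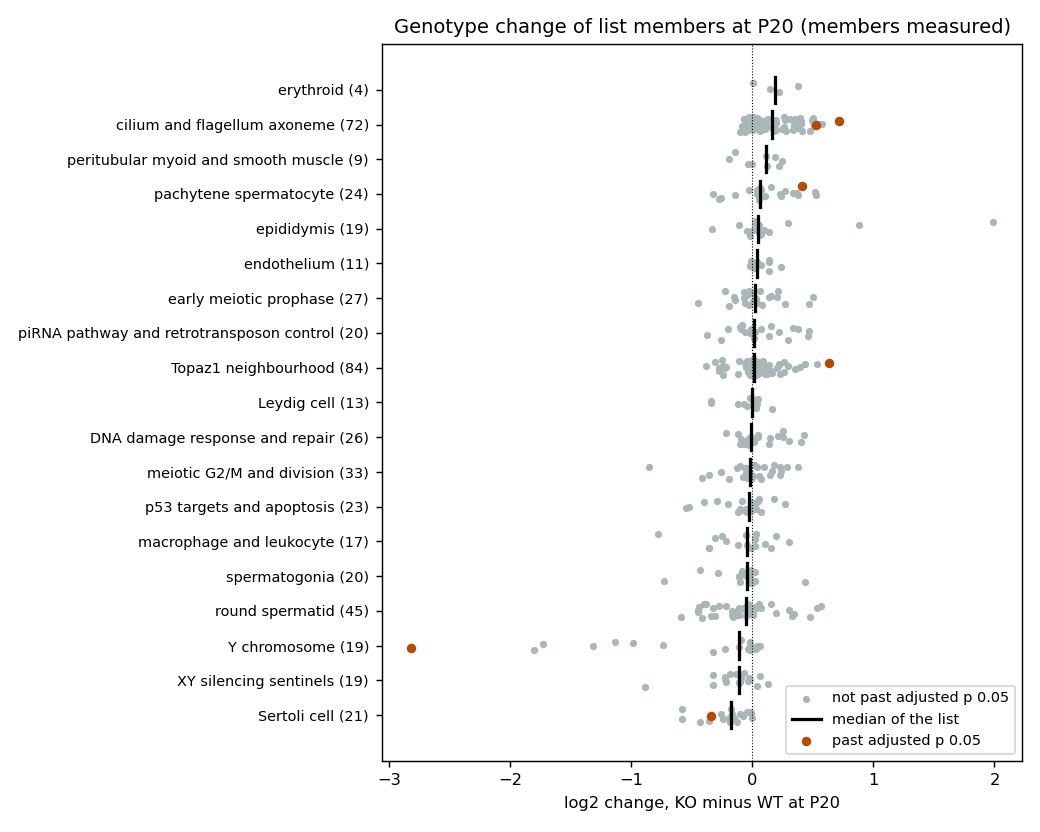
Log2 change (KO minus WT at P20) of every measured member of 19 gene lists, with a point per gene, points past an adjusted p of 0.05 in orange, and a line at each list's median. All 21 Sertoli cell members lie below 0, 57 of the 72 axoneme members lie above it, and Gm20815 of the Y chromosome list, at background in KO, is the lowest point of that list.

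In limma 472 probes passed at P20, 331 higher and 141 lower in KO. The split was 330 and 240 with normexp at an offset of 50, 164 and 134 at 16, and 215 and 192 without WT P20 replicate 1. They named 340 genes, 238 higher and 102 lower, and 111 of the probes were unnamed. At least 2-fold change was reached by 34, of which 13 were higher and 21 lower. The count was 158 without WT P20 replicate 2, 180 without KO P20 replicate 1, 253 without KO P20 replicate 2 and 267 without WT P15 replicate 2. Leaving out 1 array at a time, 15 of the 24 genes of largest change were called in all 12 fits. The Gm20815 call ended without WT P20 replicate 2 or KO P20 replicate 1 or 2 (adjusted p up to 0.0772), that of Gstt2 without WT P20 or KO P20 replicate 2 (0.0689). Cyp2e1 (0.131), Lpl (0.130), Cdk2ap2 (0.117) and Rxylt1 (0.119) were each lost without replicate 1 or 2 of either P20 group. Cyp2e1 and Rxylt1 were also lost without WT P20 replicate 3, Lpl without KO P20 replicate 3, and Lpl, Cdk2ap2 and Rxylt1 without WT P15 replicate 2. Tsc22d1 (0.148), 1700088E04Rik (0.110) and D130017N08Rik (0.101) were lost without each of the 6 P20 arrays and without WT P15 replicate 2, and Tsc22d1 also without KO P15 replicate 1. Cst9 was lost without each of the P20 arrays (0.0908), and Cfap43 without each KO P20 array, WT P20 replicate 2 or WT P15 replicate 2 (0.122). Ovol1 (0.151), Dmrtc1a (0.162), Zfp711 (0.158) and AU015836 (0.152) were each lost without each WT P15 array and replicate 1 or 2 of either P20 group. Ovol1, Dmrtc1a and Zfp711 were also lost without KO P15 replicate 2, Dmrtc1a without KO P15 replicate 1, and Zfp711 and AU015836 without replicate 3 of either P20 group. Gm5072 was lost without KO P20 replicate 1 (0.0530) and Tmem42 without WT P20 replicate 2 (0.0664).

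The lists for cilium, Sertoli cells, X and Y were called in all 12 such fits. The round spermatid call ended without WT P20 replicate 3 (adjusted p = 0.276) and under the filter for a whole group above background (0.262). That of the sex-linked sentinels ended without WT P20 replicate 1 (0.0767) and under the filters for 3 arrays (0.0728) and for a whole group (0.101). The spermatogonia call ended without WT P15 replicate 2, WT P20 replicate 1 or 3, KO P15 replicate 1 or KO P20 replicate 3 (up to 0.238), and the pachytene call without WT P15 replicate 2, WT P20 replicate 1, each KO P15 array or KO P20 replicate 1 or 3 (up to 0.322). Spermatogonia and pachytene calls also ended with KO P20 replicates 1 and 3 left out and under both filters on dim probes (0.105 and 0.172 for spermatogonia, 0.168 and 0.242 for pachytene), and that of spermatogonia under cyclic loess (0.0865).

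Whether the genotype effect differed between the ages was tested directly, as the change at P20 minus that at P15. Adipoq had the largest positive difference, 1.53 ± 0.19 on the log2 scale (SE, adjusted p = 0.0304), with -0.26 ± 0.13 at P15, and 4931406B18Rik the lowest adjusted p, 1.24 ± 0.07 (adjusted p = 0.000142). Psg23, of the pregnancy-specific glycoprotein family whose members are alike in sequence, differed by 0.80 ± 0.09 (adjusted p = 0.0267), Gm9903 by 0.72 ± 0.09 (0.0332), and Dnajc7, a co-chaperone, by 0.69 ± 0.09 (0.0478). A second probe of Mgll differed by 1.29 ± 0.15 (adjusted p = 0.0267). Negative differences were found for 4930519G04Rik (-1.11 ± 0.13, adjusted p = 0.0267), Gldnos (-1.02 ± 0.10, 0.0125), both at background in all groups but WT P20, Ifi213 (-0.90 ± 0.12, 0.0478) and Tomm40l, a mitochondrial import channel homologue (-0.55 ± 0.07, 0.0398). Trf, called at P15 and not at P20 (-0.18 ± 0.06, adjusted p = 0.265), was not shown to differ between the ages (0.48 ± 0.09, adjusted p = 0.109).

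In limma the difference passed for 25 probes, 16 positive and 9 negative, naming 18 genes, and 3202 had an unadjusted p under 0.05. The majority direction turned with normexp at an offset of 16 (14 positive, 27 negative), without WT P15 replicate 3 (6 and 11) and without WT P20 replicate 1 (17 and 52). The split was 3 and 3 with cyclic loess and 12 and 11 with 75th percentile scaling. Camera called 7 lists: up for cilium (adjusted p = 1.03e-07) and pachytene spermatocytes (0.0451), and down for the Y chromosome (5.69e-06), spermatogonia (0.00198), Sertoli cells (0.00209), the X chromosome (0.00209) and the sex-linked sentinels (0.0257). With an estimated correlation these became an adjusted p of 0.409, 0.553, 0.365, 0.410, 0.409, 0.409 and 0.442. In each of the 20 lists 0 members passed over all probes in limma. Adjusted over the list alone, Gm20815 fell in the Y list, Plk1 (-1.18) fell in the G2/M list, Cd74 (0.90) rose in the macrophage list, and Trf rose and Espn, an actin-bundling protein, fell in the Sertoli list, with 0 in the other 16. The 13 lists not called had camera adjusted p from 0.0519 (round spermatid) to 0.893 (Leydig), and among them the early meiotic, Leydig and endothelium lists had a median, mean and camera direction that differed in sign.

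The count of 25 was 2 without WT P15 replicate 2 or KO P15 replicate 2, 3 without WT P20 replicate 2, 6 without KO P15 replicate 1 or 3, 9 without WT P15 replicate 1, 11 without KO P20 replicate 3, 15 without KO P20 replicate 1, 34 without WT P20 replicate 3, 46 without KO P20 replicate 2 and 69 without WT P20 replicate 1. Of the 9 named genes only 4931406B18Rik was called in all 12 of these fits. Gldnos was lost without WT P15 or KO P15 replicate 2 (adjusted p = 0.0642 at most), and the other 7 were each lost without WT P15 replicate 2, WT P20 replicate 2, each KO P15 array or KO P20 replicate 3. Further losses were without WT P15 replicate 1 for all of them but Adipoq, WT P15 replicate 3 for all but Psg23 and Ifi213, and KO P20 replicate 1 for all but Psg23 and Tomm40l. Dnajc7 and Ifi213 were also lost without WT P20 replicate 1, these 2 and Tomm40l without WT P20 replicate 3, and Ifi213 without KO P20 replicate 2. Their adjusted p reached 0.101 for Adipoq, 0.0839 for Psg23, 0.109 for Gm9903, 0.120 for Dnajc7, 0.101 for 4930519G04Rik, 0.130 for Ifi213 and 0.121 for Tomm40l.

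The change from P15 to P20 in WT testes was measured as the reference for normal progress of the first wave. Pabpc2, a poly(A)-binding protein of germ cells, rose 45.1-fold (log2 5.49 ± 0.26, SE, n = 3 per group, adjusted p = 6.21e-07), and 1700001J11Rik 37.6-fold (5.23 ± 0.21, 2.39e-07). Catsperz, a sperm calcium channel subunit (36.9-fold), Plaat5 (32.6-fold, above background on 2 of 3 WT P15 arrays), Rasl2-9 (31.5-fold) and Adam32, a testis metalloprotease family member (31.1-fold), followed. Pdlim4, a LIM-domain protein of the actin cytoskeleton, fell 4.24-fold (-2.08 ± 0.19, adjusted p = 4.06e-05), Dlk1 3.80-fold (-1.93 ± 0.22, 0.000148), Tnfrsf12a 3.66-fold, Scx, a transcription factor found in Sertoli cells, 3.28-fold, Sel1l3 3.16-fold (1 of 2 probes opposite) and Bok, of the BCL2 family, 3.00-fold.

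The pachytene, axoneme, round spermatid, piRNA and early meiotic lists shifted upward in WT testes. At P15, Adam3 was above background on 1 of 3 WT and 2 of 3 KO arrays, Pgam2 on 2 of 3 of each, and Ccna1 on 1 of 3 WT arrays. In the pachytene list 15 of 24 members rose, 0 fell and 9 did not pass (15 rose adjusted over the list alone), led by Adam3 (log2 4.75 ± 0.14) and Spink2 (4.40 ± 0.27). The list was called up (camera adjusted p = 8.36e-09, adjusted p = 0.180 with an estimated correlation). Of 72 axoneme genes 51 rose, 1 fell and 20 did not pass, likewise adjusted over the list alone, with Cfap206 (4.04 ± 0.29) and Ttc29 (3.72 ± 0.22) in front (camera 1.34e-27, adjusted p = 0.180 with an estimated correlation). Of 45 round spermatid genes 22 rose, 0 fell and 23 did not pass (27 rose adjusted over the list alone), among them Pgam2 (4.72 ± 0.22) and Dkkl1 (3.93 ± 0.38, camera 6.04e-10, adjusted p = 0.210 with an estimated correlation). Of 20 piRNA genes 13 rose and 0 fell on either adjustment, among them Tdrd6 (4.94 ± 0.30) and Piwil1 (3.28 ± 0.57, camera 1.29e-06, adjusted p = 0.181 with an estimated correlation). The early meiotic list had 7 rises, such as Psmc3ip (1.53 ± 0.27) and Spo11 (1.24 ± 0.16), and 4 falls among 27 members (9 and 5 adjusted over the list alone, camera 0.0160, adjusted p = 0.384 with an estimated correlation).

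The spermatogonia, Sertoli, macrophage, endothelium, p53, sentinel and X lists shifted downward in WT testes. Among 20 spermatogonia genes 11 fell, such as Sohlh1 (-1.27 ± 0.18, SE) and Sall4 (-1.14 ± 0.17), 1 rose, Id4 (0.99 ± 0.13), and 8 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.00254, adjusted p = 0.326 with an estimated correlation). Falls were found for 10 of 21 Sertoli genes (12 adjusted over the list alone, Dhh -0.73 ± 0.13, camera 0.00183, adjusted p = 0.210 with an estimated correlation), 6 of 17 macrophage genes (10, Laptm5 -0.94 ± 0.16, 0.00254, 0.180) and 7 of 11 endothelial genes (8, Egfl7 -1.04 ± 0.12, 0.00233, 0.223), with 0 rises in each. Given in the same order are p53 and apoptosis genes, with 10 falls and 1 rise among 23 (10 and 1, Gadd45a -0.97 ± 0.17, 0.0346, 0.180), sex-linked sentinels, with 9 falls and 0 rises among 19 (10 and 1, Usp26 -0.91 ± 0.18, 0.00372, 0.244), and X chromosome genes, with 216 falls and 7 rises among 710 (243 and 10, Bex2 -1.45 ± 0.18, 1.09e-05, 0.180).

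Of 19 Y chromosome genes 7 rose and 1 fell in WT (8 and 2 adjusted over the list alone), with Gm20815 at least 6.65-fold, Gm20867 at least 3.38-fold and Ssty2 at least 3.31-fold higher at P20, although the list was not called (camera adjusted p = 0.0571). Other lists not called were G2/M and division (9 rose, such as Ccna1 at 3.13 ± 0.25, SE, and 3 fell, of 33, with the same counts adjusted over the list alone, camera 0.0573), DNA damage (5 and 5 of 26 on either adjustment, 0.735), Leydig (0 and 3 of 13 on either, 0.328), peritubular (0 and 3 of 9, with 4 falls adjusted over the list alone, 0.0754), erythroid (0 of 4, 0.909), epididymis (1 fall of 19, Wfdc10 at -0.63 ± 0.15, on either adjustment, 0.992) and the Topaz1 neighbourhood (14 and 14 of 84, or 15 and 18 adjusted over the list alone, 0.871). Median, mean and camera direction differed in sign for the DNA damage, erythroid and neighbourhood lists. In limma 9102 probes passed, 3750 higher and 5352 lower at P20, naming 5834 genes, while under cyclic loess more were higher (4890) than lower (3571). In the main values 1392 changed at least 2-fold, 1159 of them upward. The largest changes of 12 genes were called in all 12 fits that left out 1 array. Gm20867 and Gm20738 lost their call without WT P20 replicate 2 (adjusted p = 0.0512 and 0.0543), Wfdc10 without WT P15 replicate 1 or 2 or WT P20 replicate 3 (up to 0.0654), the early meiotic list without WT P20 replicate 1 (0.0609) and the p53 list without WT P15 replicate 3 or WT P20 replicate 1 (up to 0.0640).

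KO testes changed with age in much the same set of genes. Catsperz rose 55.7-fold (log2 5.80 ± 0.43, SE, n = 3 per group, adjusted p = 6.28e-06), Tdrd6, a tudor protein of the piRNA machinery, 50.8-fold (5.67 ± 0.30, 6e-07), Adam32 49.9-fold, Tcp10a 46.9-fold, Pabpc2 46.9-fold and Pebp4 41.8-fold. Tcp10a and Pabpc2 were above background on 1 of 3 KO P15 arrays. Pdlim4 fell 4.64-fold (-2.21 ± 0.19, adjusted p = 1.7e-05), Dlk1 4.50-fold, Wnt6, a secreted signalling protein, 3.45-fold, H2ac12 3.35-fold, Scx 3.33-fold and Mfap4 3.28-fold. Age changes in KO and WT, which share no arrays, correlated across 25287 probes above background on at least 3 of the 12 arrays (Pearson 0.95, Spearman 0.88). Probes are not independent replicates. Probes that rose in both numbered 3283 and those that fell in both 4434, against 378.1 and 829.1 for independent lists, and 3 and 7 went opposite ways. Of the 331 probes higher in KO at P20, 228 rose with age in WT (68.9%, against 8.3% of all probes) and 13 fell. Of the 141 lower probes, 61 fell with age in WT (43.3%, against 11.8%) and 39 rose (27.7%, against 8.3%). Many of all probes were at background, while 471 of the 472 called ones were above it in a whole group. Fitted alone, the 22470 probes above background in a whole group gave 3870 rises and 5898 falls with age in WT, larger shares than over all probes. The genotype and WT age comparisons also share the WT P20 arrays. The higher probes thus ran largely along the age change, while the lower probes went both ways. WT P20 replicate 1 lay behind the other P20 arrays on the first component.

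Pachytene, axoneme and piRNA lists were called up in KO testes too. In the pachytene list 16 of 24 rose and 1 fell on either adjustment (Adam3 5.29 ± 0.14, SE, Spink2 4.78 ± 0.27, camera adjusted p = 2.24e-08, adjusted p = 0.115 with an estimated correlation). Of 72 axoneme genes 52 rose and 0 fell (53 and 1 adjusted over the list alone, Ttc29 4.34 ± 0.22, camera 4.6e-27, adjusted p = 0.115 with an estimated correlation), and of 20 piRNA genes 13 rose and 0 fell (13 and 1, Piwil1 3.74 ± 0.57, 1.4e-06, 0.171). Of 45 round spermatid genes 13 rose and 0 fell on either adjustment (Pgam2 5.24 ± 0.22, Dkkl1 4.22 ± 0.38, camera 0.000137, adjusted p = 0.425 with an estimated correlation). The early meiotic list had 8 rises and 5 falls of 27 (8 and 6 adjusted over the list alone, Psmc3ip 1.79 ± 0.27) and was not called (camera 0.1002). Neither were G2/M and division (9 and 7 of 33, or 9 and 8, Ccna1 at least 7.39-fold higher, 0.233) and DNA damage (5 and 4 of 26, or 6 and 5, Mlh3 1.25 ± 0.15, 0.2997).

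Falls in KO testes covered 13 of 20 spermatogonia genes, with 1 rise (15 and 1 adjusted over the list alone, Uchl1 -1.61 ± 0.19, SE, camera adjusted p = 0.000114, adjusted p = 0.251 with an estimated correlation). They covered 16 of 21 Sertoli genes (17 adjusted over the list alone, Rhox5 -1.30 ± 0.18, camera 3.11e-05, adjusted p = 0.115 with an estimated correlation), 14 of 23 p53 and apoptosis genes with 2 rises (14 and 2, Gadd45a -1.39 ± 0.17, 0.00834, 0.115), 11 of 19 sex-linked sentinels (14, Rhox13 -1.28 ± 0.14, 0.0002, 0.171), 8 of 11 endothelial genes (8, Egfl7 -1.02 ± 0.12, 0.00834, 0.334) and 292 of 710 X chromosome genes with 4 rises (314 and 6, Bex2 -1.71 ± 0.18, 3.43e-07, 0.115). Peritubular genes were called down with 3 falls of 9 (5 adjusted over the list alone, Tpm2 -0.98 ± 0.15, 0.0309, 0.425), a call that ended without KO P15 or KO P20 replicate 2 (up to 0.0964). Not called were macrophage (7 falls of 17, or 8, camera 0.125), Leydig (4 of 13 on either adjustment, 0.338), erythroid (0 of 4, 0.596), Y chromosome (0 rises and 2 falls of 19 on either adjustment, Eif2s3y -0.83 ± 0.18 and Kdm5d -0.24 ± 0.05, 0.338) and the Topaz1 neighbourhood (15 rises and 16 falls of 84, or 15 and 17, 0.592).

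The G2/M, erythroid and neighbourhood lists had a median, mean and camera direction that differed in sign in KO. In the epididymis list 4 of 19 members rose and 2 fell with age in KO testes on either adjustment (camera adjusted p = 0.233), with Defb2 at least 4.87-fold and Adam7 at least 1.82-fold higher (adjusted p = 0.0449 and 0.0428), and both calls ended with KO P20 replicates 1 and 3 left out (log2 0.07 and 0.03). Leaving out 1 array, each was called only without KO P20 replicate 2 (adjusted p up to 0.163 and 0.140 without the others, from WT P15 replicate 1 to KO P20 replicate 3). Over all probes in limma 11581 passed in KO, 4566 higher and 7015 lower at P20, naming 7220 genes, while under cyclic loess more were higher (5149) than lower (4656). In the main values 2078 changed at least 2-fold, 1445 of them upward. With those 2 arrays left out 7088 passed (3377 higher, 3711 lower). The changes of the 12 genes of largest change were called in all 12 fits that left out 1 array.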

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

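The tests of staging, of the normalization for the round spermatid list, of a wrong label and of a sample further along the first wave, the list of adipocyte genes, and the fit without KO P20 replicates 1 and 3, were chosen only after the results were seen.

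Adipoq, Cyp2e1 and Lpl were higher in KO testes at P20, and the genotype effect on Adipoq differed between P20 and P15 by 1.526. Carry-over by 1 KO P20 library alone is argued against, since the lowest log2 change of Adipoq with any 1 of the 6 P20 arrays left out was 1.202. Fat tissue carried over into the KO P20 samples cannot be told apart from a change in the testis: the other 23 measured adipocyte genes (of 26 written) had a median change of 0.03519, the 96.84th percentile of 10000 random lists, with 16 positive. Car3 (1.15 ± 0.25 SE, adjusted p = 0.0688) and Scd1 (0.79 ± 0.26, 0.217) went with it, while Fabp4 (0.03) and Cd36 (-0.02) were not above background on any array, and 8 of the 23 genes were above background on all WT P20 arrays. Defb2 was high on KO P20 replicates 1 and 3 (10.83 and 11.14) and at 7.50 on replicate 2, where Adipoq was 9.02, while WT P20 replicate 3 had the highest WT P20 values of both (8.62 and 7.85) and WT P15 replicate 2, whose values enter the P15 term of the difference, the highest P15 values of Adipoq (8.05), Cyp2e1 (8.50), Car3 (8.25) and Scd1 (8.73).

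Camera called the round spermatid and Y lists down in KO testes at P20 although 0 of 45 and 1 of 19 members passed, and neither with an estimated correlation (adjusted p = 0.626 and 0.192), and the Y list differed between the ages by a median of -0.2199 (-0.130 without WT P20 replicate 1, -0.127 without KO P15 replicate 2). An earlier stage of the KO testes as a whole would lower pachytene and cilium genes that rise in WT. Their median was instead 0.2656 higher in KO (57 of 66 members, and 0.17 to 0.36 leaving out 1 array). Both lists had already been called up at P20, so this sign was known beforehand and is not independent support. A delay limited to later germ cells is not addressed by these genes. Quantile normalization is argued against for the Y list alone, which kept a negative median under 75th percentile scaling and cyclic loess, the higher being -0.1019. Gm20815 was at -2.78 and -2.76 in these settings. Neither subtracts background, so they do not test its absence. The round spermatid median was 0.005329 under 75th percentile scaling. That sign does not decide, since the scaling also put the median of all probes at 0.0626 (6.18e-05 in the main values). Camera still called the list down there. WT P20 replicate 1 lay below WT P20 replicates 2 and 3 for Gm20815 (8.90 against 10.77 and 11.11), Ssty2 (8.00 against 9.68 and 10.08) and Odf1 (7.69 against 8.33 and 8.63), and the brighter spermatid genes Catsper2 (0.47) and Odf2 (0.33) had positive changes that did not pass. No biological explanation was tested, and the genotype stays open as one.

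KO P15 replicate 1 lay among the WT P15 arrays on the second component, and without it 154 probes passed at P15 in place of 2. By mean Spearman coefficient all 3 KO P15 arrays were closer to the WT P15 arrays than to their own group, replicate 1 the most. The own-group means of replicates 2 and 3 include replicate 1. KO P15 replicates 1, 2 and 3 had 0.916, 0.905 and 0.903 with the WT P15 arrays. With their own group they had 0.903, 0.901 and 0.898. A wrong genotype label is argued against, because over 5 probes that fell at least 4-fold at P20 and were above background on all WT P15 arrays its median position was 0.004255 on a scale from the other KO P15 arrays (0) to WT P15 (1). C2cd4a, 1 of the 5, did not separate the genotypes at P15, since KO P15 replicate 3 (9.96) lay among the WT P15 arrays (8.64 to 10.27). That it was further along the first wave is a candidate explanation: its deviation from the other KO P15 arrays correlated at 0.4056 with the WT change from P15 to P20. Values as large were found for WT P15 replicates 1 and 3 (-0.44 and 0.51) and WT P20 replicates 1 and 3 (-0.54 and 0.53) along the KO change, so that the value is not particular to this array, and other sources of its deviation were not tested.

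The other named effects that differed between the ages follow, taken by the rule for named genes. 4931406B18Rik differed by 1.236. Psg23, whose family is alike in sequence, differed by 0.8012, Gm9903 by 0.7196 and Dnajc7 by 0.6897. Outside that rule, a second probe of Mgll differed by 1.29 ± 0.15 (SE, adjusted p = 0.0267), and Abcg8 (0.69), Bnip5 (0.68), Abca15 (0.66), Mpo (0.65), Sfmbt2 (0.62), Kif9 (0.57), Spata16 (0.45) and Ammecr1l (0.38) passed too, named after their values were seen. Negative differences were -1.106 for 4930519G04Rik, -1.023 for Gldnos, -0.9025 for Ifi213 and -0.5539 for Tomm40l. Of the 9 genes taken by the rule, Adipoq included, only 4931406B18Rik was called whichever array was left out, and the arrays whose omission ended the other calls are named in the results. The genes outside the rule were not followed one by one across these fits. Gldnos was lost without WT P15 or KO P15 replicate 2 (adjusted p = 0.0642 at most). Median differences of called lists were -0.1621 for spermatogonia, 0.1076 for pachytene spermatocytes, 0.2319 for the axoneme, -0.1805 for the sex-linked sentinels, -0.1972 for Sertoli cells and -0.03339 for the X chromosome. Leaving out 1 array moved these medians by over 1.5 times as follows. Spermatogonia were at -0.254 without KO P15 replicate 1 and -0.0792 without KO P15 replicate 3. Pachytene spermatocytes were at 0.221 without WT P15 replicate 1, 0.30 without KO P15 replicate 1 and 0.0337 without KO P15 replicate 3. The axoneme was at 0.132 without WT P15 replicate 3 and 0.141 without WT P20 replicate 1. The sentinels were at -0.0892 without WT P20 replicate 1, -0.0682 without KO P15 replicate 2 and -0.0901 without KO P20 replicate 3. Sertoli cells were at -0.120 without KO P20 replicate 3 and the X chromosome at -0.0198 without KO P15 replicate 2. None of these lists was called with an estimated correlation (adjusted p = 0.409 at the lowest, and 0.365 for the Y list). The pachytene call ended without WT P15 replicate 3, WT P20 replicate 1, KO P15 replicate 2 or 3, or KO P20 replicate 1 or 3 (up to 0.365), and its median was -0.0126 without WT P15 replicate 3. The call of the sentinels ended without WT P15 replicate 1, WT P20 replicate 1, KO P15 replicate 2 or KO P20 replicate 1 (up to 0.3005), that of spermatogonia without KO P15 replicate 3 (0.0695) and that of X without KO P15 replicate 2 (0.129).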

How the results depend on the processing

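Leaving out KO P20 replicates 1 and 3 was chosen only after the results were seen, and normexp, cyclic loess, 75th percentile scaling and the filters on dim probes were unplanned tests added once neqc and detection filters could not be run.

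At P15, 2 probes passed in the main values. The count was 6 with normexp at an offset of 50, 8 with normexp at 16, 1 with cyclic loess, 4 with an intensity trend, 1 with either form of replicate block, 1 with the mean over a gene's probes, 1 at a fold of at least 2, and 1 without KO P20 replicates 1 and 3. A limma fit of only the 2 groups gave 0, with 2731 at an unadjusted p under 0.05. Leaving out 1 array gave from 1 (without WT P15 replicate 2, KO P15 replicate 3 or KO P20 replicate 2) to 154 (without KO P15 replicate 1).

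At P20, 472 probes passed. The count was 298 with normexp at an offset of 16 (164 higher, 134 lower, 206 shared), 905 with array weights, 267 and 108 with the replicate number as a block over all arrays or within age or genotype, 234 for the mean over a gene's probes, 34 at a fold of at least 2, and 130 without KO P20 replicates 1 and 3. Whether the replicate numbers pair the samples is not settled. Deviations from the group mean of like-numbered arrays correlated over probes at -0.33, -0.04 and -0.32 at P15 and 0.20, -0.07 and 0.04 at P20. Between the ages they correlated at -0.37, 0.04 and -0.17 in KO and at 0.09, 0.13 and 0.15 in WT. Unlike numbers reached 0.36, 0.25 and 0.41, but only 0.04 for age in WT, so a pairing there is not excluded. The Trf call at P15 ended with either block. The blocks kept 20 and 11 of the 33 named P20 results and 1 of the 9 named differences each. With the block over all arrays the pachytene and spermatogonia calls at P20 ended (adjusted p = 0.0610 each), and the round spermatid and epididymis lists were called for the difference (0.0430 and 0.0461). Leaving out 1 array gave from 158 (WT P20 replicate 2) to 612 (KO P15 replicate 3), with 180 without KO P20 replicate 1, 253 without KO P20 replicate 2 and 267 without WT P15 replicate 2. Cyclic loess gave 422 probes (385 shared), normexp at 50 gave 570 (392 shared), 75th percentile scaling 605 (386 shared) and the authors' values 528 (464 shared). The share of higher probes was 70.1% in the main values, 57.9% with normexp at 50 and 55.0% at 16. Of 33 named P20 results, 28 were kept with cyclic loess, 26 with normexp at 16 and 10 without KO P20 replicates 1 and 3.

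The difference between the ages passed for 25 probes. The count was 41 with normexp at 16, 6 with cyclic loess, 67 with an intensity trend, 1 and 2 with the blocks, 15 for the mean over a gene's probes, 6 at a fold of at least 2, and 62 without KO P20 replicates 1 and 3. Leaving out 1 array gave from 2 (WT P15 or KO P15 replicate 2) to 69 (WT P20 replicate 1). The share of positive differences was 64% in the main values, 34.1% with normexp at 16, 50% with cyclic loess and 52.2% with 75th percentile scaling.

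The age counts of 9102 in WT and 11581 in KO became 5569 and 6900 for the mean over a gene's probes, 1392 and 2078 at a fold of at least 2, and 7088 in KO without KO P20 replicates 1 and 3. The share that rose was 41.2% in WT and 39.4% in KO, and 57.8% and 52.5% with cyclic loess.

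With an estimated correlation 0 lists were called in any of the 5 comparisons, so the list calls of camera rest on its preset correlation. At P15 the 1 called list became 3 with 75th percentile scaling, 2 with normexp at 50 or 16, and 1 to 5 leaving out 1 array (5 without WT P15 replicate 1). At P20 the 8 called lists became 5 with a filter for 3 arrays above background, 4 with a filter for a whole group, and 5 (without WT P20 replicate 1) to 10 (without KO P20 replicate 2) leaving out 1 array. For the difference 4 to 9 lists were called leaving out 1 array, against 7. The axoneme, Sertoli, X and Y calls at P20 ended only with an estimated correlation among the settings run. The P20 pachytene call also ended with the authors' values, 75th percentile scaling and normexp, the P20 spermatogonia call with cyclic loess, and the WT early meiotic call with 75th percentile scaling.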

Other observations

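None of the tests given here was chosen after its result was seen.

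Other splits of the arrays were counted, with the real split included in each count. Of the 10 splits of 6 arrays, 1 gave as many probes as the real one at P15 (2, highest other 0), 1 at P20 (472, highest other 1), 1 for age in WT (9102, highest other 0) and 1 for age in KO (11581, highest other 0). With 10 splits a share under 0.1 cannot be reached. For the difference between the ages, 7 of 100 drawn splits of genotype within age, the real one among them, gave at least 25 probes. The highest other gave 647. That split put WT P15 replicates 1 and 2 with KO P15 replicate 3 and exchanged the WT and KO labels at P20. All 7 kept the P20 arrays of each genotype together and so carried the whole P20 genotype effect. Where the labels were exchanged, its sign was turned. With the true P15 groups that contrast is the sum of the effects at both ages, not their difference (232 probes). Such splits are not free of the genotype effect, so the count does not decide whether chance is excluded.

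Probes past the threshold at P20 had the same sign at P15 in 67.16% of cases (317 of 472), 61.6% of the higher and 80.1% of the lower. Of the 20 labellings of the P15 arrays 4 gave a share as high, up to 71.4%, so chance is not excluded. The effects at P15 and P20, which share no arrays, correlated at 0.32 over 25287 probes.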
